A study of Homo sapiens with 6 samples.

How the data were processed

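RNA of NCI-H522 cells, an established human lung cancer line, was measured on 6 Affymetrix expression arrays. The cells had been transduced with a vector for BRG1 (gene SMARCA4, the ATPase of the SWI/SNF chromatin remodelling complex), for the type II TGFβ receptor (TβRII, gene TGFBR2), or for both; per the labels both genes were put back into these cells. For each of the 3 transduced lines there was 1 array of cells given TGFβ for 2 h and 1 array of cells without it, so every group held 1 array. The labels of the BRG1 array name no TGFβ but do not call the cells untreated. They were taken as the cells without TGFβ. The title of the BRG1 array with TGFβ holds a letter v that its partner's title lacks and that the labels do not explain. Whether these 2 arrays differ in more than TGFβ is therefore not known.

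The deposited values are linear signal intensities, 1 per probe set and array; per the labels' protocols they come from total RNA turned into biotin-labelled cRNA with standard Affymetrix labelling. The software that summarised the probes, its background correction and its detection calls are not given in the sources used here. The mean of each deposited column, leaving out the lowest and highest 2% of values, was 499.9, so the authors' table had been scaled to a common level per array. That scaling was kept. Median intensities ran from 84.6 to 125.4 and the number of arrays, not a read depth, limits the precision.

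The table held 54675 probe sets, of which 62 were array controls. The platform annotation gave 1 gene symbol to 41097 probe sets, several to 1801 and none to 11777. Symbols were updated by Entrez gene number through a RefSeq gene table of assembly GRCh38.p14, in which 41043 probe sets were matched. Probe sets with several symbols or none were not named and were not used for genes. A background floor was set on each array as the 90th percentile of 208 probe sets of olfactory receptor, bitter taste receptor, keratin-associated protein and beta-defensin genes, which lung cells should not express. The floors were 155.3 (BRG1), 186.8 (BRG1 with TGFβ), 139.6 (BRG1+TβRII), 253.1 (BRG1+TβRII with TGFβ), 140.1 (TβRII) and 222.4 (TβRII with TGFβ), so each TGFβ array had a higher floor than its partner. Values below the floor were set to it and log2 was taken. In the limma models a gene below the floor on both arrays of a line therefore carries the difference of their floors as a TGFβ response. Of the 19775 genes, each was represented by the probe set with the highest mean. The 12181 genes above the floor on at least 1 array were tested. Where the dimmer side lay below the floor, the difference is a lower bound and is written as at least N-fold.

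With 1 array against 1, the TGFβ response of each line is a difference of log2 values without a replicate check, and no p-value is given for it. Genes were counted when above the floor on at least 1 of the 2 arrays and different by a log2 value of at least 1. The other comparisons used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, Benjamini-Hochberg adjusted p under 0.05). An additive model with a term per line and 1 TGFβ term, with 2 residual degrees of freedom, gave the differences between lines and the mean TGFβ response. Its prior had 4.91 degrees of freedom and an SD of 0.158. A second model gave the single-vector lines 1 shared TGFβ response and the BRG1+TβRII line an extra one. It had 1 residual degree of freedom and a prior of 4.08 degrees of freedom with an SD of 0.141, and it takes any difference between the single-vector responses as noise. Nothing in the labels says that the 6 cultures were grown separately, and the arrays of a line with and without TGFβ are not replicates. Adjusted p-values therefore measure only the spread between these arrays, which may be technical.

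A total of 21 gene lists were fixed before the data were examined. For each list the median log2 difference of the measured members is given with its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these arrays. For the limma contrasts the lists were also tested with camera, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a contrast. No camera call at the preset correlation held with the estimated one. With an estimated correlation camera takes the residual degrees of freedom of the model (2 or 1), so hardly any list could pass. Hypoxia genes in BRG1 added to TβRII cells had an estimated correlation of 0.00562, under the preset. Their camera adjusted p still went from 0.00281 to 0.362. The lost calls therefore decide nothing, and the calls at the preset correlation rest on that assumed value. Also before the data were examined, the genes to be named were fixed as the 15 largest increases and 10 largest decreases after TGFβ in the BRG1+TβRII line, the 5 largest each way in each single-vector line and up to 10 each way past the threshold in each limma contrast. Where fewer than 10 passed in a contrast between lines, places went to genes at least 2-fold different the same way with and without TGFβ. For these and for the TGFβ responses the brighter value had to be at least 2 times the floor. SMARCA4 and TGFBR2 are always named, members of the lists may be named, and a gene with another probe set going the other way by over 0.5 is said to disagree.

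The alternatives were quantile normalization, median centring, no floor, a floor 2 times higher, log2 of the value plus the floor, only genes above the floor on all 6 arrays, the mean of a gene's probe sets, every probe set on its own, limma with a variance trend (also robust), no term for the line, the second model for the differences between lines, each TGFβ condition on its own and leaving out each array. A floor common to all arrays, median centring of the lists and choosing the probe set again under each floor or scaling were added after the data, among them the floors and first gene counts, had been seen. The models were tested on simulated arrays of 12181 genes with 100 genes changed by a log2 of 1 and 100 by a log2 of 2, under each of 2 assumptions about the spread. With spreads drawn from the fitted prior, the extra response of the BRG1+TβRII line was called for 0% of genes at either size. With each gene's own moderated SD it was called for 77% and 100%, with 47 false calls. The simulation with the moderated SD came first, and the other was added after its false calls had been seen. For the mean TGFβ response the shares were 87% and 99% with the prior and 100% at both sizes with the moderated SD. For BRG1 added to TβRII cells they were 60% and 99%, then 95% and 100%. For TβRII added to BRG1 cells they were 67% and 100%, then 99% and 100%. For BRG1 against TβRII cells they were 69% and 98%, then 99% and 100%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.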

Results

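The data are 6 arrays of NCI-H522 lung cancer cells, 1 for each combination of vector (BRG1, TβRII or both) and TGFβ treatment (none, or 2 h). On each array 35.5% to 42.5% of the probe sets lay above the background floor. The 4 arrays of BRG1-carrying cells resembled one another, with Spearman correlations of 0.945 to 0.960 across probe sets, and the 2 TβRII arrays had a correlation of 0.954. The lowest, 0.945, was between the BRG1+TβRII arrays with and without TGFβ. With the BRG1-only arrays, the treated BRG1+TβRII array had 0.958 and 0.959, and the untreated one 0.953 with each. Between BRG1-carrying and TβRII-only cells the correlation was 0.907 to 0.917. These are correlations across probe sets, which are not independent replicates. The ratio of 3′ to 5′ signal for the actin control was 1.30 to 1.35 on the 4 arrays of BRG1-carrying cells and 1.11 and 1.14 on the TβRII arrays, so it differed with the line. For the GAPDH control it was 1.03 on the BRG1+TβRII array with TGFβ and 0.943 to 0.958 on the other 5.

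SMARCA4, which encodes BRG1, had its brightest probe set at 5415 (BRG1), 5628 (BRG1 with TGFβ), 7078 (BRG1+TβRII) and 5798 (BRG1+TβRII with TGFβ), against 319.5 (TβRII) and 379.8 (TβRII with TGFβ). The mean was 17.1-fold higher in BRG1-carrying cells, in 4 of 4 arrays against 2 of 2. Of the 8 other SMARCA4 probe sets, the 6 above the floor on at least 1 array were not higher in BRG1-carrying cells, at 0.573-fold to 0.912-fold of the TβRII level. The remaining 2 lay below the floor on every array. One of them read 74.3 to 95.3 in BRG1-carrying and 34.4 to 36.9 in TβRII-only cells, and the other 26.2 to 48.7 and 53.3 to 76.0. What part of the transcript each probe set covers is not given in the sources used here. TGFBR2, which encodes the ligand-binding TGFβ receptor, was at 341.0 (TβRII), 338.9 (TβRII with TGFβ), 994.8 (BRG1+TβRII) and 558.2 (BRG1+TβRII with TGFβ) on its brightest probe set, and below the floor on both BRG1-only arrays, at 7.97 and 4.14. The difference between the BRG1+TβRII and BRG1 lines is at least 4.38-fold. The other TGFBR2 probe set read 236.4 to 255.2 on the 4 arrays of BRG1-carrying cells, above the floor on 3 of them, and 83.5 to 94.4, below the floor, in TβRII-only cells, so it did not follow the receptor vector.

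**Figure D1:**
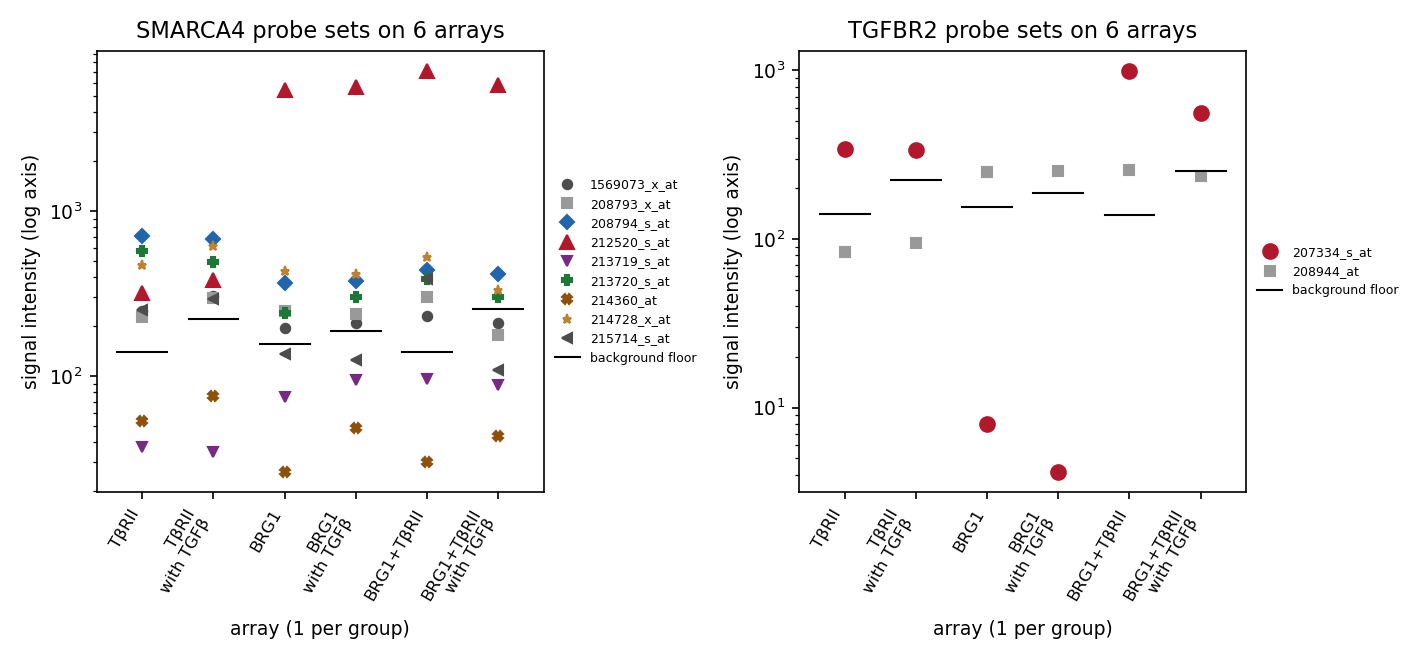
Signal intensity (log axis) of each SMARCA4 probe set, left, and each TGFBR2 probe set, right, on the 6 arrays, with the background floor of each array as a black line. The large red symbols are the brightest SMARCA4 probe set, at 5415 to 7078 on the 4 arrays of BRG1-carrying cells and 319.5 to 379.8 on the others, and the brightest TGFBR2 probe set, which lies below the floor on both BRG1-only arrays.

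The first question was how cells carrying both vectors responded to TGFβ. After 2 h, known immediate targets of TGFβ signalling were higher on the treated array. JUNB, an AP-1 transcription factor subunit, was 4.91-fold higher (5810 against 1184), PDGFB, a growth factor, 4.90-fold, SMAD7, the inhibitory SMAD that feeds back on the receptor, 3.93-fold (5556 against 1415), and SKIL, a SMAD co-repressor, 3.81-fold. The developmental transcription factors DLX2 (4.23-fold), FOXS1 (3.33-fold) and HES1 (3.37-fold, a Notch target) were higher too, as were the AP-1 subunit FOS (3.51-fold), the lysosomal regulator TFEB (3.69-fold) and FAM43A (3.83-fold). FOS without TGFβ read 160, close to the floor of that array (139.6). Its log2 difference was 1.81, and 1.15 with 1 floor for all arrays. The remaining genes of the 15 largest increases were RAD51D, a homologous recombination gene (5.36-fold), ARFGAP3, a Golgi trafficking gene (3.33-fold), LINC02941 (at least 4.95-fold), DEFB124 (at least 4.22-fold) and ANHX (at least 3.89-fold). For RAD51D, ARFGAP3 and LINC02941 the untreated array lay below the BRG1-only arrays. RAD51D read 1543 with and 288 without TGFβ, against 1277 and 934 on the BRG1-only and 365 and 424 on the TβRII arrays, and ARFGAP3 read 2334 and 700, against 1688 and 2167 on the former and 1232 and 2075 on the latter. LINC02941 read 691 with TGFβ and 83.2, below the floor, without it, against 383 and 261 on the BRG1-only arrays. DEFB124 is one of the beta-defensin genes used to set the floor.

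Of the 34 measured early TGFβ-induced genes, 30 were higher with TGFβ in the BRG1+TβRII line and 10 by at least 2-fold. Their median log2 difference was 0.62, above the middle 95% of random lists (-0.19 to 0.03), at the 100th percentile. Beyond those above, PMEPA1 (1.49), BHLHE40 (1.46), GADD45B (1.41), IL11 (1.36), NEDD9 (1.03) and EDN1 (1.02) were at least 2-fold higher. CDKN1A, the cell cycle inhibitor p21, differed by 0.79 and CCN2 by 0.84. In the list of genes that TGFβ commonly represses, the median was 0.09 over 14 members, above random lists (-0.30 to 0.06). The largest differences in it were upward, in HES1 (1.75) and TXNIP (1.06). Immediate early genes, which answer many stimuli, had a median of 0.13, above random lists (-0.22 to 0.07). Of them 14 of 21 were higher, including IER3 (1.55) and DUSP2 (1.19). S phase genes had a median of -0.18, inside the range of random lists (-0.18 to 0.09), with 19 of 24 lower.

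The largest decreases in the BRG1+TβRII line were smaller. They were PIP5K1A, a lipid kinase (2.70-fold lower), the clathrin adaptor subunits AP1S1 (2.45-fold) and AP2B1 (2.30-fold), PAGR1 (2.41-fold), the prolyl isomerases FKBP10 (2.35-fold) and FKBP8 (2.24-fold), HIRA, a histone chaperone (2.27-fold), SURF2 (2.27-fold), RWDD2B (2.23-fold) and ING1, a chromatin reader (at least 3.25-fold). For PIP5K1A and ING1, 1 other probe set disagreed. In the BRG1 pair AP2B1 (-0.91 on the log2 scale), ING1 (-0.78), HIRA (-0.74), PIP5K1A (-0.68), AP1S1 (-0.44) and FKBP10 (-0.39) were lower too. SURF2 (-0.05) and RWDD2B (-0.06) hardly differed there, and PAGR1 (0.14) and FKBP8 (0.05) went the other way. A need for the receptor vector is not shown for the genes lower in both pairs. Over 11460 genes, 191 were at least 2-fold higher and 21 lower, and 139 and 19 were so among the 10084 genes above the floor on both arrays. After quantile normalization the split was 104 higher and 29 lower, and with 1 floor for all arrays 77 and 21. The treated array had the highest floor of the 6, and its 18S ribosomal RNA control (3′ probe set) read 16525 against 894.2.

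**Figure D2:**
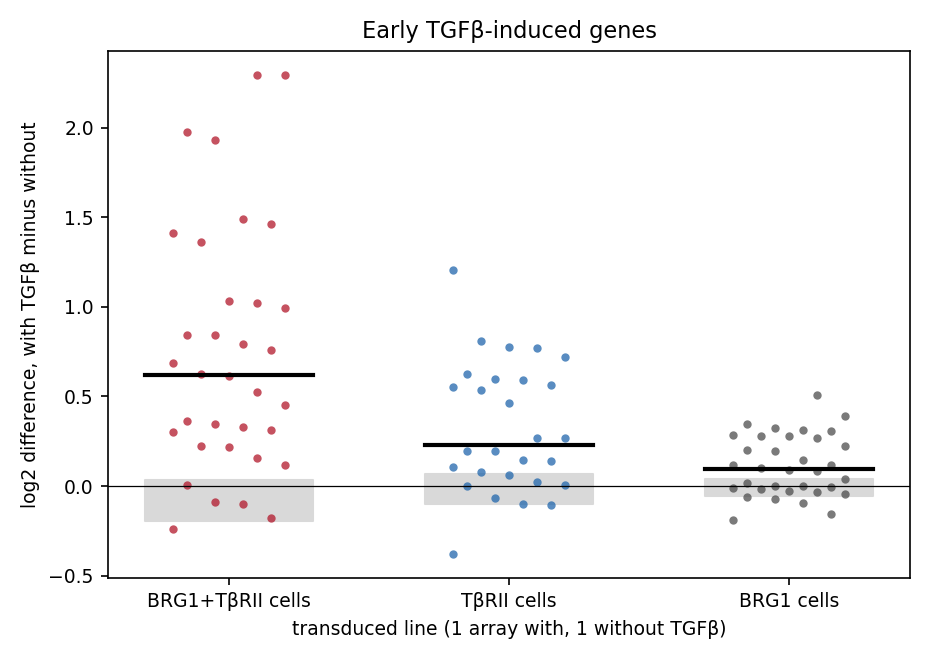
Log2 difference with TGFβ minus without, 1 array each, for every measured gene of the early TGFβ-induced list (points) in the 3 transduced lines, with the list median (black line) and the middle 95% of medians of 10000 matched random lists (grey). The medians are 0.62 in BRG1+TβRII cells (34 genes), 0.23 in TβRII cells (28 genes) and 0.10 in BRG1 cells (34 genes).

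Cells with a single vector were the comparison for whether both genes are needed. In the BRG1 line, in which the brightest TGFBR2 probe set was below the floor, few genes differed after TGFβ. Of 11408 genes 6 were at least 2-fold higher and 5 lower, and the SD over the 10638 genes measured on both arrays was 0.190, against 0.358 in the BRG1+TβRII line. The largest increases were ANHX (at least 3.03-fold), CHAF1A, a chromatin assembly factor (2.25-fold), TFAP4 (2.22-fold), SH3BP2 (1.95-fold) and RNA45SN5, the ribosomal RNA precursor (1.90-fold). The largest decreases were MED18 (at least 2.69-fold), RAB4B (at least 2.53-fold), ANK1 (2.18-fold), LRRC43 (2.13-fold, 1 other probe set disagreed) and KLK10 (at least 2.12-fold). The early TGFβ-induced list had a median of 0.10, which also lay above random lists (-0.06 to 0.04), at the 99.99th percentile. In this list 23 of 34 members were higher, none by 2-fold. ANGPTL4 (0.51), IL11 (0.39) and PDGFB (0.35) led it. JUNB differed by 0.08 and SMAD7 by 0.22. Interferon response genes had a median of 0.10, with 24 of 32 higher. The 18S control read 22263 with TGFβ and 1001 without.

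In the TβRII line, SMAD7 was 1.21 higher on the log2 scale with TGFβ, PDGFB 0.81, PMEPA1, a TGFβ feedback inhibitor, 0.77 and KLF10 0.77. Of the 28 measured early TGFβ-induced genes 24 were higher, with a median of 0.23, at the 100th percentile of random lists (-0.10 to 0.07). The 4 measured immune markers of this pair, all dim, were higher too, with a median of 0.83, above random lists (-0.03 to 0.67). Immediate early genes had a median of 0.20, above random lists (-0.09 to 0.13), with 17 of 23 higher, led by FOSB (1.33) and NR4A3 (0.94). The list of genes that TGFβ commonly represses had a median of 0.20, above random lists (-0.05 to 0.17), with 11 of 12 higher. In this pair the induced and the repressed list thus both shifted upward. The largest increases of all genes were ERN2 (at least 3.69-fold), ESS2 (at least 3.52-fold), ATP8B1 (3.46-fold), CLDN19 (3.37-fold) and STX17-DT (3.10-fold). The largest decreases were PYGB, brain glycogen phosphorylase (3.25-fold), the kinase MARK4 (2.85-fold), GPANK1 (2.34-fold), LINC00857 (2.31-fold) and PPP2R2D (at least 2.17-fold, 1 other probe set disagreed). Of 10896 genes 84 were at least 2-fold higher and 10 lower, which became 33 and 12 after quantile normalization, 138 and 6 after median centring and 16 and 7 with 1 floor for all arrays. The treated array had a floor of 222.4 against 140.1.

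Whether the response of cells with both vectors differed from that of single-vector cells was tested in the second model. Early TGFβ-induced genes had a larger response in the BRG1+TβRII line, with a median extra log2 response of 0.41 and 27 of 34 members above 0 (camera adjusted p = 2.91e-05, and adjusted p = 0.856 with an estimated correlation). The lines also differed in TGFBR2. Its brightest probe set was higher by a log2 of 1.13 in BRG1+TβRII than in TβRII cells (limma adjusted p = 0.0120). In BRG1 cells it lay below the floor. An effect of BRG1 on the response therefore cannot be told apart from one of receptor level. JUNB had an extra response of 1.97 ± 0.29 (SE), PDGFB 1.72 ± 0.28 and SKIL 1.48 ± 0.24. These 3 passed when adjusted over the list alone, and none did when adjusted over all genes (limma adjusted p = 0.714 for each). In the list of immediate early genes, JUNB, FOS (1.62 ± 0.23), DUSP2 (1.47 ± 0.26) and IER3 (1.43 ± 0.29) passed when adjusted over the list alone, and in the list of genes that TGFβ commonly represses HES1 did (1.35 ± 0.22, upward). Without and with TGFβ, SKIL read 4345 and 6554 in TβRII cells, against 1832 and 6986 in BRG1+TβRII cells. FOS read 555 and 598, against 160 and 560. Between these 2 lines the treated levels of both genes were close, and the difference in response rests mainly on a lower untreated level in BRG1+TβRII cells. In BRG1 cells, SKIL read 1936 without and 2407 with TGFβ, and FOS 143 and 102, below the floor. Against that line the difference lay in the treated arrays. In TβRII cells JUNB read 2027 and 3002, against 1184 and 5810 in BRG1+TβRII cells, and PDGFB 165 and 290, against 439 and 2153. Interferon response genes had a median extra response of -0.30, with 24 of 32 below 0 (camera adjusted p = 0.000864, and adjusted p = 0.856 with an estimated correlation). Only 15 of the 32 were above the floor on an array of the TβRII pair. The others carry the difference of its floors (140.1 and 222.4) as a TβRII response, which lowers their extra response. With 1 floor for all arrays the median was -0.10, and in the BRG1+TβRII pair alone it was -0.10 over 31 members, inside the range of random lists (-0.17 to 0.08). No member passed over the list alone. Limma called 0 of 12181 genes, with 816 at an unadjusted p under 0.05, where 609 would be so by chance. With the BRG1 or the TβRII line set apart in place of the BRG1+TβRII line there were 663 and 560. With a variance trend it called 197 (92 higher and 105 lower), and 168 with the robust trend. The 0 calls without a trend do not show that no gene differed. In the simulation with spreads drawn from the prior, this test called 0% of genes changed by a log2 of 1 or 2. With the moderated SD it called 77% and 100%.

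With the trend, the extra response was at least 2-fold above 0 for 36 genes and at least 2-fold below 0 for 14. The former included JUNB, DLX2, FAM43A, PDGFB, SKIL, IER3, HES1, SMAD7, PIM1 and HBEGF. This fit rests on 1 pair of BRG1+TβRII arrays and 1 residual degree of freedom. With the BRG1 or the TβRII line set apart instead it called 7 and 55 genes, so its calls for the BRG1+TβRII line are not evidence of a difference gene by gene. The 14 genes below 0 included DDIT3, a stress-induced transcription factor (-1.39), and PIP5K1A (-1.42). PIP5K1A differed by -1.43 in the BRG1+TβRII pair, by -0.68 in the BRG1 pair and by 0.67 in the TβRII pair. PIM1 and HBEGF were named after their values had been seen. By this fit 9 of 34 early TGFβ-induced genes were called higher and none lower. The 9 were SMAD7, SKIL, SKI, PMEPA1, BHLHE40, JUNB, CCN2, GADD45B and PDGFB. It also called 5 immediate early genes higher and 1 lower, and the interferon response genes IFIT1, IFIT2 and OASL and the keratins KRT8 and KRT18 lower. KRT8 and IFIT1 were below the floor on both TβRII arrays and carry the difference of those floors, which lowers their extra response. That was -0.69 for KRT8 and -1.03 for IFIT1, against -0.33 and -0.68 in the BRG1+TβRII pair alone.

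Averaged over the 3 lines, TGFβ gave the early induced list a median of 0.34, with 29 of 34 members above 0 (camera adjusted p = 5.46e-05, and adjusted p = 0.714 with an estimated correlation). PDGFB stood at 1.15 ± 0.33 (SE), SMAD7 at 1.13 ± 0.29, SKIL at 0.95 ± 0.29 and GADD45B at 0.82 ± 0.20. In this list 13 genes passed when adjusted over the list alone and 0 over all genes. COL12A1, a fibril-associated collagen, stood at 0.83 ± 0.11 and was 0.75, 0.92 and 0.83 higher in the BRG1, BRG1+TβRII and TβRII lines. It alone of 20 extracellular matrix genes passed over the list alone. Of immediate early genes FOSB (0.82), NR4A3 (0.69) and NR4A1 (0.60) did. S phase genes had a median of -0.07, inside the range of random lists (-0.11 to 0.02), with 19 of 24 below 0 (camera adjusted p = 0.0347, and adjusted p = 0.714 with an estimated correlation). The 6 measured immune markers, all dim, had a median of 0.57 (camera adjusted p = 0.000364, and adjusted p = 0.714 with an estimated correlation), inside the range of matched random lists (0.38 to 0.58), on arrays whose floors were higher with TGFβ. All 6 passed when adjusted over the list alone, as did the fibroblast marker LUM (0.62) and the endothelial marker VWF (0.47). Limma called 0 genes, with 2233 at an unadjusted p under 0.05 and a smallest adjusted p of 0.102. It called 95 with a variance trend and 271 with the robust trend. Without the BRG1 array or the BRG1 array with TGFβ it called 1302 genes, 1280 of them higher, and without either TβRII array 2. Without a BRG1 array the TGFβ term rests on the BRG1+TβRII and TβRII pairs. Their floors rose from 139.6 to 253.1 and from 140.1 to 222.4 with TGFβ. Genes below the floor on both arrays of a pair carry these rises as a response. The 1302 calls are therefore not a count of TGFβ-induced genes, and the share due to the floors was not tested.

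Next came the question of how BRG1+TβRII cells differed from TβRII cells. Each vector combination was 1 transduced line, and no array held cells without a vector. An effect of BRG1 therefore cannot be told apart from other differences between the lines. Here and in the next paragraphs, genes that rose or fell were higher or lower in BRG1+TβRII than in TβRII cells. The actin control differed between these lines as given above. ARHGAP29 rose at least 108-fold, and CRYAB, a small heat shock protein, 84.0-fold (6.39 ± 0.14 on the log2 scale). CD44, the hyaluronan receptor and a gene known to need BRG1 or its paralog, rose at least 79.8-fold, and KRT8, an epithelial keratin, at least 64.1-fold. PODXL, a sialomucin, rose 60.9-fold. The interferon-induced IFIT1 rose at least 63.8-fold and IFIT3 by at least 5.73 on the log2 scale. The aldo-keto reductases AKR1C2 and AKR1C1 rose 86.0-fold and 52.8-fold, as uncertain values for near-identical paralogs. TAGLN2, an actin-binding protein above the floor on 1 of the 2 TβRII arrays, rose by 5.59 ± 0.31 on the log2 scale. Limma's adjusted p for these 10 genes lay between 1.21e-05 and 4.37e-05.

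Among single genes that fell, EGR4 fell at least 17.6-fold and EGR1 9.53-fold (from 9862 and 11613 to 992 and 1272), and the transcription factors GBX2 and ZIC1 fell 9.22-fold and 8.84-fold. EPHA5, an ephrin receptor of neurons, fell 13.1-fold, SCLT1, a centriole protein, 13.0-fold and RGCC, a cell cycle regulator, 8.94-fold. RIPPLY3 fell at least 9.67-fold. PDE4A and LIN7A, below the floor on 1 of the 2 BRG1+TβRII arrays, fell by 3.14 and fell by 3.01 on the log2 scale. Limma's adjusted p for these 10 lay between 1.52e-05 and 8.29e-05. In all, limma called 4874 of 12181 genes, 2315 higher and 2559 lower, of which 1114 and 714 differed by at least 2-fold. Without the TβRII array it called 3200.

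Interferon response genes were higher as a group in the BRG1+TβRII line. All 32 measured members were above 0, 30 passed the threshold (30 also when adjusted over the list alone), and the median was 2.25, against -0.29 to 0.22 for random lists. ISG15 rose by 5.17 and IFI6 by 5.05. Genes known to depend on BRG1 or its paralog BRM had a median of 2.20. Of 17 measured, 13 rose, among them TIMP3 (4.73), IFITM1 (4.65), LCN2 (4.56), MMP2 (3.40) and CSF1 (2.84), and VIM and RARB fell (14 and 2 when adjusted over the list alone). For these lists camera gave an adjusted p of 3.14e-17 and of 8.88e-08, and adjusted p = 0.362 and adjusted p = 0.378 with an estimated correlation.

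Proliferation genes were lower. Of 24 S phase genes 23 fell, the exception CHAF1A standing at -0.64, and the median was -1.22. CDC45, a replication helicase factor, fell by 1.90, CCNE2, a G1/S cyclin, by 1.76 and the helicase subunit MCM7 by 1.65. Of 24 mitosis genes 21 fell, with a median of -0.85, among them the motor KIF11 (-1.66) and cyclin A2, CCNA2 (-1.57). Adjusted over the list alone the counts were also 23 and 21. Camera gave an adjusted p of 2.50e-11 and of 1.31e-07, and adjusted p = 0.362 and adjusted p = 0.378 with an estimated correlation.

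Epithelial and matrix genes moved in both directions. Of 16 epithelial markers 9 rose and 3 fell, with a median of 0.84. KRT18 rose by 5.14, E-cadherin (CDH1) by 4.25 and KRT7 by 2.46, whereas LSR fell by 1.13, OCLN by 0.75 and TJP1 by 0.49. Of 20 extracellular matrix genes 9 rose, led by LAMB3 (3.16), TIMP1 (3.02), LOXL2 (2.95) and FBN1 (2.28), and 2 fell, COL3A1 (-1.05) and COL5A2 (-0.45). Of 11 mesenchymal markers 4 rose, including TAGLN (3.13) and S100A4 (3.10), and 3 fell, including ZEB1 (-1.47), a repressor of epithelial genes. Of 8 neuroendocrine or neuronal markers 2 rose, SCG5 (1.73) and ENO2 (1.08), and 3 fell, including CHGA (-1.26) and CHGB (-1.10). Adjusted over the list alone, 10 epithelial and 12 matrix genes rose, and the other counts of these 4 lists were unchanged. Camera gave an adjusted p of 0.00318 for epithelial and 0.00102 for matrix genes (adjusted p = 0.43 for each with an estimated correlation). Mesenchymal and neuroendocrine markers did not pass (adjusted p = 0.408 and adjusted p = 0.999).

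In the metabolic and stress lists, set against 4874 calls among all 12181 genes, only some shifted as a whole. Of 23 hypoxia genes 11 rose, among them NDRG1 (3.80), DDIT4 (2.99) and BNIP3L (2.57), and 2 fell. Of 14 cholesterol biosynthesis genes 9 rose, including INSIG1 (1.19), LSS (1.16) and SC5D (1.13), and none fell. Of 27 unfolded protein and amino acid response genes 12 rose, including the cystine transporter SLC7A11 (2.13), and 6 fell. Of 20 p53 targets 8 rose, including GADD45A (4.69) and CDKN1A (1.70), and 3 fell. Of 25 SWI/SNF subunits SMARCA4, the vector's gene, rose by 4.20 ± 0.17 and 11 fell, including BCL7A (-1.99), SS18L1 (-1.03) and ARID1A (-0.76). Of 12 heat shock genes 2 rose and 3 fell, and of 25 immediate early genes 7 rose, including JUN (3.51) and ATF3 (2.93), and 11 fell. Adjusted over the list alone, 9 p53 targets rose and 5 fell, 12 SWI/SNF subunits fell, and the other counts stood as given. Camera gave an adjusted p of 0.00281 for hypoxia and 0.00583 for both the cholesterol and the SWI/SNF lists (adjusted p = 0.362 for each with an estimated correlation). The p53, unfolded protein, immediate early and heat shock lists did not pass (adjusted p = 0.192, 0.255, 0.4 and 0.661).

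Of 34 early TGFβ-induced genes 19 rose and 6 fell, with GADD45A, NEDD9 (3.56) and PDGFB (2.15) rising (camera adjusted p = 0.00318, and adjusted p = 0.637 with an estimated correlation). Of 14 genes that TGFβ commonly represses 3 rose and 7 fell (camera adjusted p = 0.209, and adjusted p = 0.743 with an estimated correlation). Of 21 receptors, ligands and SMADs 7 rose, including LTBP1 (2.28), SMAD3 (1.42) and TGFBR2 itself (1.13), and 3 fell (camera adjusted p = 0.324, and adjusted p = 0.637 with an estimated correlation). The markers of other cell types gave no common shift. Of 7 fibroblast markers 2 rose and 1 fell, of 6 immune markers none was called, and of 4 endothelial markers TEK fell by 2.96, with medians of 0.13, 0.07 and 0.18. Adjusted over the list alone, 20 induced genes and 8 receptors, ligands and SMADs rose, with no other change.

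**Figure D3:**
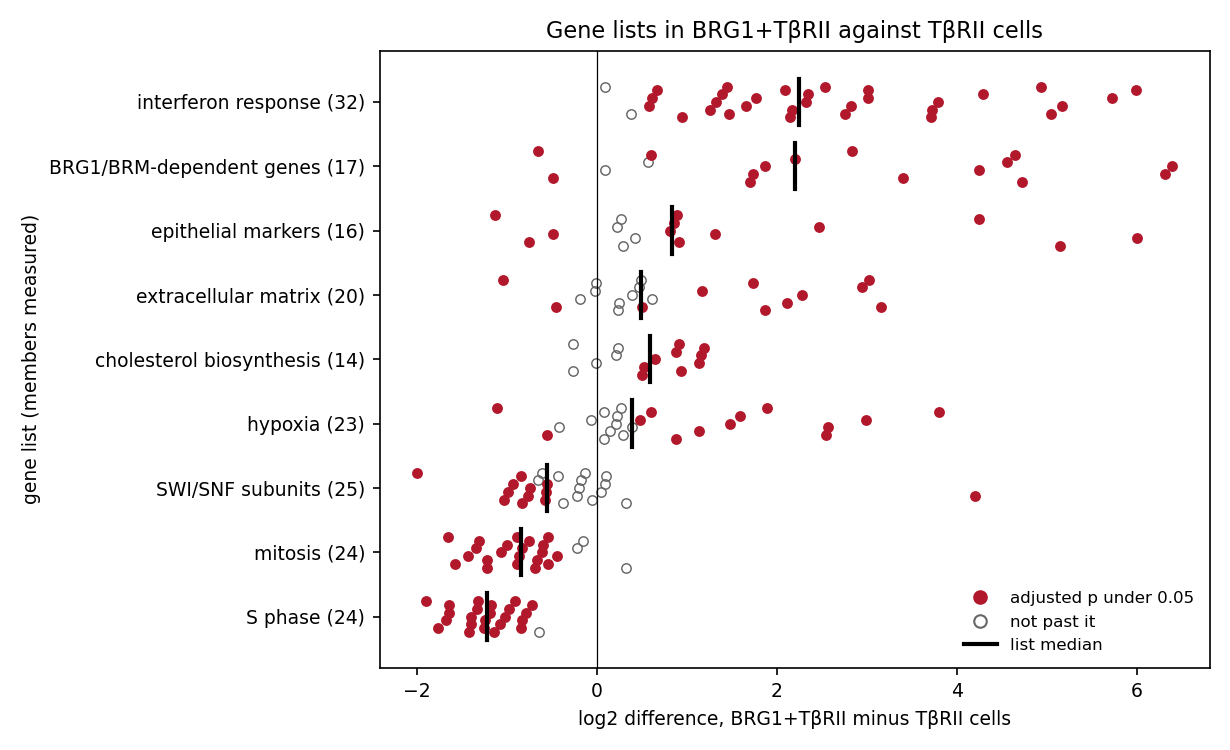
Log2 difference between BRG1+TβRII and TβRII cells from the additive model (x axis) for the measured members of 9 gene lists (points, filled where limma's adjusted p was under 0.05), with list medians as black bars. Interferon response genes centre on 2.25 and S phase genes on -1.22, and the single SWI/SNF subunit far to the right is SMARCA4 itself, at 4.20.

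The receptor added to BRG1 cells gave 0 calls in limma. TGFBR2 was at least 4.38-fold higher, and the matrix metalloproteinases MMP1 (2.78-fold), MMP3 (2.48-fold) and MMP2 (2.19-fold) were higher both with and without TGFβ. So were PPP1R14C (2.30-fold), SELENBP1 (2.23-fold), EVA1A (2.18-fold) and ITGA2, a collagen receptor subunit (at least 2.32-fold). SCGB1A1, the club cell secretoglobin, was 2.15-fold lower and INHBB, an activin subunit, 2.13-fold lower. MMP1 read 6419 and 4839 in BRG1+TβRII cells against 1870 and 2154 in BRG1 cells. None passed the threshold, with limma adjusted p from 0.556 for TGFBR2 and MMP2 to 0.935. TGFBR2, the added vector's own gene, was thus missed at a log2 difference of at least 2.13. The 0 calls therefore do not show that no gene differed. The recovery given for this contrast in the simulations cannot be carried over to these arrays. Of 12181 genes 578 were at an unadjusted p under 0.05. Limma called 58 with a variance trend, 115 with the robust trend, 1 with no floor and 10 without either TβRII array.

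Gene lists in that contrast shifted by small amounts. It averages the arrays with and without TGFβ, so a TGFβ response of the BRG1+TβRII line enters it. Early TGFβ-induced genes had a median of 0.27, with 29 of 34 above 0, mitosis genes 0.19, with 20 of 24 above 0, hypoxia genes 0.14, with 18 of 23 above 0, and extracellular matrix genes 0.15, with 15 of 20 above 0. For leading members of the first list the difference lay in the treated arrays. SKIL read 1832 in BRG1+TβRII and 1936 in BRG1 cells without TGFβ, but 6986 and 2407 with it, and SMAD7 1415 and 1368, but 5556 and 1597. That median therefore does not show an effect of the receptor without TGFβ. Interferon response genes had a median of -0.26, with 31 of 32 below 0, led by MX1 (-0.69) and OAS1 (-0.59). No member of these lists passed, over all genes or over the list alone. Camera gave adjusted p of 9.95e-08, 0.000546, 0.00532, 0.0194 and 1.33e-10 in that order, and adjusted p = 0.76 for each with an estimated correlation. Over the list alone, TGFBR2 passed among receptors, ligands and SMADs, and MMP2 and IFITM1 (-0.75) among BRG1- or BRM-dependent genes.

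The single-vector lines were also set against each other. In BRG1 cells, ARHGAP29 (at least 103-fold), CD44 (at least 80.8-fold), CRYAB (79.3-fold), KRT8 (at least 62.2-fold) and PODXL (60.6-fold) were higher than in TβRII cells, as were IFIT1 (at least 78.2-fold), IFIT3 (at least 77.6-fold), AKR1C2 and AKR1C1 (88.2-fold and 53.9-fold, uncertain as before) and TAGLN2 (5.86 on the log2 scale). EGR4 (at least 19.5-fold), GBX2 (at least 14.8-fold), SCLT1 (11.4-fold), LIN7A (11.3-fold), EGR1 (9.77-fold), DLX2 (9.70-fold), PDE4A (9.38-fold), RIPPLY3 (8.57-fold) and the angiopoietin receptor gene TEK (8.44-fold) were lower, and EPHA5 by -3.87 on the log2 scale. Limma's adjusted p for these 20 genes was at most 0.00144. It called 4957 genes, 2352 higher and 2605 lower, and 3223 without the BRG1 array. Interferon response genes had a median of 2.54, with 31 of 32 called higher, and all 24 S phase genes were called lower, with a median of -1.32 (31 and 24 also when adjusted over the list alone). Camera gave an adjusted p of 9.85e-20 and of 2.14e-11, and adjusted p = 0.381 for both with an estimated correlation. This contrast uses the same TβRII arrays as that of BRG1 added to TβRII cells, so the calls of one are not separate evidence for the other.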

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

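Chosen only after the result was seen were the tests with 1 floor for all arrays and the test that set the BRG1+TβRII genes against the BRG1-only arrays. The bounds for the background and for handling were written with the floors, the gene counts of the pairs and, for the TβRII line, the list medians in view, but before the values that they judge had been computed.

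The early TGFβ-induced genes responded differently in the BRG1+TβRII line and in the single-vector lines, with a median extra log2 response of 0.41 in the test of the difference. The lines also differed in TGFBR2 level, so an effect of BRG1 on this response cannot be told apart from one of the receptor. Interferon response genes had a median extra response of -0.30, but 17 of 32 were below the floor on both TβRII arrays and carry the difference of those floors, and with 1 floor for all arrays it was -0.10. Both lists passed camera with its preset correlation (adjusted p = 2.91e-05 and adjusted p = 0.000864) and neither did with an estimated correlation (adjusted p = 0.856 for each). With 1 residual degree of freedom that loss decides nothing. The TGFβ arrays of the BRG1-carrying lines stood out in a control that no comparison used. The 3′ probe set for 18S ribosomal RNA read 16525 (BRG1+TβRII with TGFβ) and 22263 (BRG1 with TGFβ), against 266.8 to 1001 on the other 4 arrays, 1 of which was also TGFβ-treated. RNA45SN5, the ribosomal RNA precursor, went from 965.9 to 2368 and from 1087 to 2067 in the same pairs, and from 774.1 to 897.6 in the TβRII pair.

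Many more genes were at least 2-fold higher than lower after TGFβ in the BRG1+TβRII line. A higher background on the treated array could add such genes: with 1 floor for all arrays the ratio of higher to lower genes was 3.67 (77 and 21), between the bounds of 2 and 5 written for and against that explanation, so it stays open. Low values on the untreated array are a candidate explanation for most of them, since only 34 of the 191 higher genes were also at least 2-fold above the mean of the BRG1-only arrays. Genes picked for a large difference in 1 pair favour that outcome, which limits how much it shows. In the TβRII line STX17-DT (1.63), SMAD7 (1.21), PDGFB (0.81) and PMEPA1 (0.77) were also higher with TGFβ, so a need for both vectors is not shown for them.

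In cells with the receptor but no BRG1 vector, the early TGFβ-induced list was also higher after TGFβ. Among the 25 members above the highest floor on both arrays the median was 0.267, above the random lists (-0.12 to 0.05), but less than 2 bootstrap SDs (0.148 each) above 0, so a higher background on the treated array stays open. Without immediate early genes, which handling or serum can raise, the median of 25 members was 0.197 with a bootstrap SD of 0.134, and that explanation stays open too. The 4 immune markers, all dim, were also higher in this pair, with a median of 0.83. In the BRG1 pair the list without immediate early genes had a median of 0.116 over 31 members, above random lists (-0.06 to 0.05). Immediate early genes of that pair had a median of -0.02, with 9 of 21 higher. A response to TGFβ through the receptor alone could account for the list in the TβRII line as well and was not tested apart from the other explanations.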

How the results depend on the processing

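The settings with 1 floor for all arrays, with the probe set chosen again and with median centring of the lists were chosen after the data had been seen. For BRG1 added to TβRII cells and for BRG1 against TβRII cells, quantile normalization, median centring and 1 floor for all arrays shared 4421 to 4806 of 4874 calls and 4536 to 4911 of 4957, all with the same sign. Every probe set on its own gave 8146 and 8570, and at least 2-fold differences without a test were 2109 and 2173 without TGFβ and 1761 and 1807 with it. Leaving out 1 array gave 3200 (without TβRII) to 4730 and 3223 (without BRG1) to 5031. For TβRII added to BRG1 cells limma called 0 with most settings, 1 with no floor, 58 with a trend, 115 with the robust trend and 0 to 10 (without either TβRII array) when 1 array was left out. At least 2-fold differences were 60 without TGFβ (21 higher and 39 lower) and 60 with it (51 and 9). The extra response had 197 calls with a trend and 168 with the robust trend, and the mean response 95 and 271. Leaving out 1 array gave the mean response 0 to 1302 calls, the latter without either BRG1 array, where floor differences of the other lines enter as a response. The TGFβ counts of single pairs (212, 11 and 94 in the BRG1+TβRII, BRG1 and TβRII lines) depended on the handling of dim values. They were 346, 96 and 208 with no floor, 75, 1 and 15 with a floor 2 times higher, 98, 3 and 23 with 1 floor for all arrays, 114, 4 and 41 for genes above the floor on all 6 arrays, 481, 36 and 207 by probe set, and 26, 1 and 9 for log2 differences of at least 1.5. Quantile normalization gave 133 (BRG1+TβRII) and 45 (TβRII), median centring 144 (TβRII), and the mean of probe sets 6 (BRG1). The cause was not tested. Of the list medians 208 stayed within their spread, 39 moved and 3 changed sign, all 3 for the mean TGFβ response with 1 floor for all arrays: TGFβ-repressed genes at -0.00149, BRG1- or BRM-dependent genes at -0.00465 and interferon response genes at -0.0203. Of the values for named genes 1547 were the same, 144 moved, 42 came past the threshold and 1 fell short of it. With the probe set chosen again, as in the first run, 2 of 474 changed sign: TGFBR2 in TβRII added to BRG1 cells at -0.0353 with no floor and ANK1 in the BRG1 pair at 0.0350 with log2 of the value plus the floor. All 29 camera calls were lost with the estimated correlation, an outcome that the few residual degrees of freedom made nearly certain. Leaving out an array leaves no residual degrees of freedom or no estimate for the extra response, and no difference for a single pair. The additive model compares TGFβ within each line, and without the term for the line limma also called 0 genes for the mean response. Signal over background limits the dim genes, since at most 42.5% of probe sets lay above the floor.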

Other observations

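The tests with 1 floor for all arrays and the counts of genes above all other BRG1-carrying arrays were chosen after the result was seen. The bounds for scaling, neighbouring genes and other splits were written with the gene counts of the contrasts in view, but before the values that they judge had been computed.

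Several other gene lists also passed camera between the BRG1 and TβRII lines. Of 17 BRG1- or BRM-dependent genes 12 were higher in BRG1 cells and 2 lower in limma, with a median of 2.27. Of 16 epithelial markers 9 were higher and 2 lower (median 0.94), of 23 hypoxia genes 8 and 3 (0.19), of 20 extracellular matrix genes 10 and 2 (0.54), and of 14 cholesterol biosynthesis genes 9 and 0 (0.59). Of 24 mitosis genes 21 were lower, with a median of -0.96, and of 25 SWI/SNF subunits 9 were lower and SMARCA4, the vector's gene, was higher by 3.99. Adjusted over the list alone the counts were 13 and 2, 10 and 2, 8 and 3, 11 and 2, 9 and 1, 22, and 9 and 1. Camera gave adjusted p of 7.92e-08, 0.0023, 0.0347, 0.00409, 0.00974, 1.25e-08 and 0.013 in that order. With an estimated correlation adjusted p = 0.381, except for adjusted p = 0.436 (epithelial) and adjusted p = 0.511 (matrix). The remaining 12 lists did not pass camera (adjusted p from 0.095 to 0.898).

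With 1 floor for all arrays, 23 of the 77 genes higher after TGFβ in the BRG1+TβRII line were also at least 2-fold above each of the 3 other arrays of BRG1-carrying cells. JUNB stood 2.29 above the highest of them on the log2 scale, DLX2 2.08, SMAD7 1.80, PDGFB 1.59, FOXS1 1.56 and SKIL 1.54. Besides genes named above, they included CSRNP1 (1.24), DLX1, a homeobox gene (1.22), HEY1, a Notch target (1.21), RARA, a retinoic acid receptor (1.10), NOG, a BMP antagonist (1.01), and SPSB1. These genes were named after their values had been seen, and the TβRII-only arrays did not enter the count. On those DLX2 read 8528 without and 10365 with TGFβ, against 4460 on the BRG1+TβRII array with TGFβ.

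The many differences between BRG1-carrying and TβRII-only cells could come from array scaling or background, but the lowest count under quantile normalization, median centring and 1 floor for all arrays was 4625, against 4874, which argues against that as the whole cause. Different chromosome copies, or cells of another origin, may also set lines apart. Medians of 91 windows of 100 neighbouring genes had an SD of 0.102, above all 1000 permutations of gene order (highest 0.0862), but only 1 window lay beyond 0.3 where the bound asked for at least 5. The smaller BRG1+TβRII against BRG1 difference also exceeded its permutations (0.0221 against 0.0198), while the TGFβ difference within the TβRII line did not (0.0255 against 0.0310), and neighbouring genes can share regulation, so this stays open beside an effect of BRG1 itself.

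For the mean TGFβ response the real split of the 6 arrays into 3 and 3 gave 0 genes past the threshold, which all 10 splits match whatever they hold (the highest of the others was 0), so this count decides nothing. Only 3 of the other splits put 1 array of each line on either side. They gave 565, 102 and 178 genes at an unadjusted p under 0.05, against 2233 for the real split, in which every TGFβ array also has the higher floor. There are too few splits for a share under 0.05.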
